A study of Rattus norvegicus with 12 samples.

How the data were processed

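Total RNA from the livers of male Wistar rats, 5 weeks old per the labels, was converted to biotin-labelled cRNA from 2 ug of RNA and hybridised to Affymetrix arrays, per the labels' protocols. After 4 days on the basal diet, rats received 20% maple syrup or 20% sugar mix syrup in the diet for 11 days. Of the 12 arrays, 6 are from each diet, and each is labelled a biological replicate. The groups were taken from the labels, which give no batch.

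The deposited table is the authors' processed value for each of 31099 probe sets on the 12 arrays, with 0 missing values, and is treated here as a score. The summarization and normalization that made it are not given in the sources used here. Levels ran from 5.56513 to 15.2071 and resemble log2 intensities, and the arrays' quantiles are nearly identical. The differences between arrays are far smaller than log2 intensities give: the median standard deviation of a probe set over the 12 arrays was 7.14e-06, and only 3 probe sets had a range over 1. The spread differs between probe sets. It also differs within a gene. In the 122 genes whose second most variable probe set had wide spread too, the larger standard deviation was a median of 1.66 times the smaller. The median correlation of these probe sets was 0.93. Between genes, unequal compression and unequal variation between animals were not told apart, and the cause of the compression is not known here. A difference in this score is therefore not a log2 ratio, no fold is reported, and a test that compares differences between genes on the raw scale favours probe sets with wide spread. The design had assumed log2 values. The test fixed for it was kept because it uses each gene's own spread. It also moves each gene's variance toward a trend shared across genes (prior degrees of freedom 0.649). Its p values therefore still depend in part on unequal spread. For example, Asl and Atp5f1b had a similar Hedges' g (-1.67 and -1.64) but a moderated t of -3.23 and -1.92. Their diet means differed by -0.000122 and -6.25e-07. In simulations with the real spreads and independent genes the test controlled false calls. Control where genes vary together was not simulated.

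Probe sets were named through the platform annotation and the RefSeq gene table: 20832 had 1 gene symbol, 436 had several and were not named, and 9831 are unnamed here. The 57 control probe sets were left out. For each of 14217 genes the probe set with the highest mean over all 12 arrays was used, and 4526 genes had more than 1. No filter on low values and no further normalization was applied.

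Diets were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjusted p of 0.05 over all genes). Because differences carry no unit, effects are given as Hedges' g with a 95% interval from the noncentral t distribution, and as the number of the 36 pairs of 1 animal of each diet in which maple syrup was higher. Figures were drawn with matplotlib 3.10.9. Gene lists, 49 in all, 37 of pathways and 12 of cell markers or tissue handling, were fixed before the data were examined, and 1142 of the 1385 memberships written were measured. They were tested with limma's camera with a preset correlation of 0.01, with lists of at least 5 measured genes. The camera test was repeated with the correlation as limma estimates it and with a correlation estimated from residuals scaled to each gene's own spread; the latter was chosen after limma's own estimate had been seen. Exact permutation tests used all 924 arrangements of the animals and cannot give a p under 0.002165.

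The rule for named genes, fixed beforehand, took the genes with the largest differences among those that passed or, as none did, the 10 with the smallest p; up to 4 members with the smallest p of each list called by camera; and a fixed set of genes of liver metabolism and stress, some of which are not reported here.

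The tests were tried on simulated data with the real spreads, in 5 rounds over 14217 genes; 6 of 161 limma calls were false. With no simulated difference limma and camera made a median of 0 calls, where genes were simulated as independent. Alternatives were quantile normalization, median centring, a floor at the 20th percentile, a filter on the lowest 30% of genes, other rules for probe sets, other variance models, array weights, the replicate number as a block, each array left out, a minimum difference of 0.5, rank products, and fry in place of camera. Chosen after seeing the data were a rescaling of each gene's range by its root of power 4 (after a factor of 340, an assumed form of the compression), exact permutation of list scores, the removal of genes shared between lists and the correlation from scaled residuals. The number of arrays limits the precision, and detection calls were not used here.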

Results

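Liver gene expression was measured on 12 Affymetrix arrays, each from 1 male Wistar rat, a commonly used outbred laboratory strain. In 6 rats the purified diet contained 20% maple syrup, and in the other 6 it contained 20% of a syrup mixed from sugars to a similar sugar composition. The diets were given for 11 days and were followed by a fast of 16 hours. The labels state that 7 rats were fed maple syrup and 8 the sugar mix; the animals beyond the 6 arrays per diet were not analysed here. Each array held 31099 probe sets, from which 14217 named genes were taken. The number of arrays limits the precision. Array medians lay between 7.36619 and 7.36632, a gap that is wider than the median range of a probe set over the 12 arrays (2.38e-05). The deposited levels resemble log2 intensities, but the differences between animals were far smaller than log2 intensities give. Compression may differ in degree between probe sets. In 122 genes with 2 probe sets of wide spread, the larger standard deviation was a median of 1.66 times the smaller. The degree of compression itself was not measured. No fold change is therefore given. The size of a difference is stated as Hedges' g, the difference between the diet means (maple syrup minus sugar mix) in units of the standard deviation between animals.

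The comparison asked which liver genes differed between rats fed maple syrup and rats fed a syrup of similar sugars; the title given to the series refers to protection of the liver. No single gene passed the test, and 7 gene groups stood lower with maple syrup in a test that treats their members as nearly independent; none did with a correlation from scaled residuals. These groups were genes of the interferon response, the proteasome, antigen presentation, the periportal zone of the liver lobule, the urea cycle, gluconeogenesis and oxidative phosphorylation. Among single genes, Pck1 encodes the cytosolic phosphoenolpyruvate carboxykinase of gluconeogenesis. It was higher in the maple syrup animal in 2 of the 36 pairs made of 1 animal of each diet. The g of Pck1 was -1.91 (95% interval -3.22 to -0.55, 6 animals per diet). Pck1 had the smallest p of the measured genes fixed beforehand, and this interval makes no allowance for that choice. The diet means differed by -1.67e-06 in the deposited score, at a level of 14.13. Ghr, the growth hormone receptor, was picked for its small p and was higher in 34 of 36 pairs. Its g was 2.31 (95% interval 0.84 to 3.73, with no allowance for this choice). Neither Pck1 nor Ghr passed after adjustment over all genes. The moderated t of Pck1, -3.50 as deposited, became 0.28 under median centring, where the mean of all genes became 0.31. Array medians differed by more than Pck1 varied, so this change cannot decide the direction of Pck1.

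With limma and Benjamini-Hochberg adjustment, 0 of 14217 genes were higher and 0 were lower at an adjusted p of 0.05, and the smallest adjusted p was 0.429. At an unadjusted p of 0.05, 616 genes would be counted, 297 higher and 319 lower with maple syrup, where chance alone gives 711. In 14 genes all 36 pairs went one way, and chance gives 30.8. Rank products, a test on the ranks of differences, called 521 genes from the same values, but it called a median of 457.5 genes in simulated data without any difference that kept each gene's spread. In simulations of this design limma recovered 38.79% of genes shifted by 3 standard deviations, 7.761% of those shifted by 2 and 0.2985% of those shifted by 1, so differences of the last size were not detectable with these animals.

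The 10 genes with the smallest p did not pass the test. They were picked by p from the same data, so their g is expected to be too large. Their 95% intervals do not allow for this choice. Members named for the called lists below were also picked by p. Nmur2, a receptor for neuromedin U, had g = 3.61 (95% interval 1.70 to 5.45) and was higher with maple syrup in all 36 pairs, with an adjusted p of 0.429 in limma. Scaf11, a splicing-related gene, had g = 4.24 (95% interval 2.11 to 6.32), also with all 36 pairs higher, and an adjusted p of 0.686. Hacd1, an enzyme of fatty acid elongation, had g = 2.85, with an adjusted p of 0.975. Rwdd3 (g = 2.72), Hsd17b1 (g = 2.50), an enzyme that forms estradiol from estrone, Dexi (g = 2.48) and Ghr were also higher with maple syrup, and Lilra5 (g = -2.43), Ripor2 (g = -2.35) and F2r (g = -2.31), a thrombin receptor, were lower. Second probe sets gave g = 1.69 for Hacd1 and 1.75 for Ghr, in the direction of the first. The other probe sets were far smaller in the remaining genes that had them: g lay between 0.04 and 0.88 for Scaf11 and was 0.18 for Rwdd3 and -0.45 for Ripor2. Under quantile normalization the moderated t of Nmur2, Scaf11, Hsd17b1 and Dexi changed sign. The diet means of these genes differed by only 7.35e-06 (Scaf11) to 2.12e-05 (Hsd17b1) in the deposited score. This normalization also left 964 genes constant, so at this size a changed sign does not decide a direction.

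**Figure D1:**
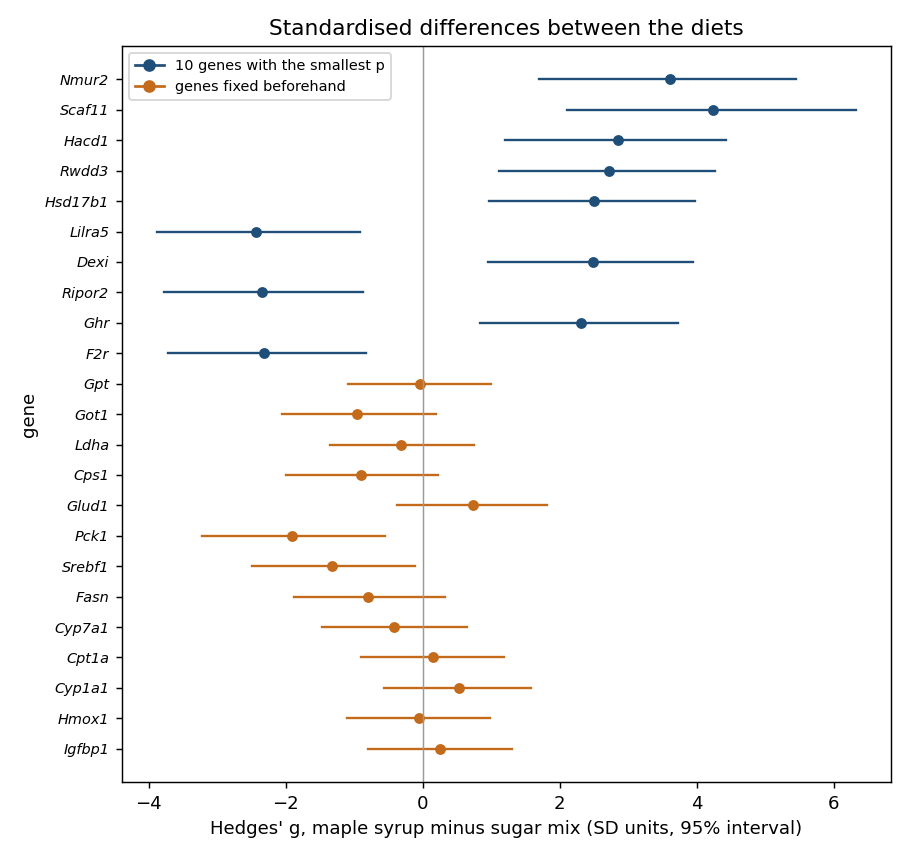
Hedges' g (horizontal axis, in standard deviations between animals, maple syrup minus sugar mix) for the 10 genes with the smallest p and the genes fixed before the data were examined. Points are estimates from 6 animals per diet and lines are 95% intervals. Those of the 10 genes do not allow for their choice by p. Pck1 lies at -1.91 and Ghr at 2.31, and none of the genes passed the test over all genes.

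Genes of liver metabolism fixed beforehand did not pass either. Among those of sugar and fat metabolism, Srebf1, a transcription factor of lipid synthesis, had g = -1.32 (95% interval -2.49 to -0.11). Fasn, the fatty acid synthase, had g = -0.80 from its brighter probe set and 0.02 from the other. Cpt1a, which admits fatty acids to mitochondria, had g = 0.15, and Ldha, lactate dehydrogenase, had g = -0.31. Of the genes for enzymes that are measured in blood as signs of liver injury, Gpt had g = -0.04 and Got1 had g = -0.96. For nitrogen handling, Cps1, the first enzyme of the urea cycle, had g = -0.90 (95% interval -2.00 to 0.23). Glud1, glutamate dehydrogenase, had g = 0.74 (95% interval -0.37 to 1.81). The estimates for these genes that form or use ammonia had opposite signs, but neither direction was established. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had g = -0.42, Cyp1a1 0.53, Igfbp1 0.26 and Hmox1 -0.06. Apart from Srebf1, the 95% intervals of all genes named in this paragraph included 0, for Fasn from its brighter probe set.

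Of the 49 gene lists fixed before the data were examined, 7 passed camera, a test of whether a list is shifted against the other genes, with a preset correlation of 0.01 between genes, and all 7 were lower with maple syrup. With a correlation estimated from scaled residuals none passed, and each of the 7 had an adjusted p of 0.963. This shared value comes from the adjustment over the 49 lists. Before adjustment, p in that camera test ran from 0.0222 for periportal genes to 0.523 for oxidative phosphorylation. With the correlation as limma estimates it, the proteasome list alone passed, with an adjusted p of 0.0482. limma's estimate for this list was -0.0153, while the mean correlation between its members from scaled residuals was 0.57. In an exact permutation of the animals, two-sided, the smallest adjusted p was 0.957. Before adjustment the exact permutation p was 0.316 for the proteasome, 0.0758 for the urea cycle, 0.0606 for gluconeogenesis and 0.422 for oxidative phosphorylation. No member of any list passed over all genes. Adjusted over the list alone, 1 gene in 1 list passed: Ghr, in the growth hormone and IGF axis. This adjustment does not span the 49 lists, so 1 such call can arise by chance.

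The interferon response, genes switched on by antiviral signalling, had 32 of 34 measured members lower and 2 higher, with a median g of -0.47 and a camera adjusted p of 0.00105. With the estimated correlation the adjusted p was 0.963, and the exact permutation p of the list score was 0.286. Gbp4, a guanylate-binding protein, had g = -1.16, and Igtp, an interferon-induced GTPase, had g = -0.95. In antigen presentation, 20 of 22 members were lower, with a median g of -0.59 and a camera adjusted p of 0.00145; the adjusted p with an estimated correlation was 0.963 and the exact permutation p was 0.0974. Tap2, a peptide transporter, had g = -1.12, and Psmb9, a subunit of the immunoproteasome that is also in the interferon list, had g = -0.95. In the proteasome list 32 of 34 members were lower, with a median g of -0.48 and a camera adjusted p of 0.00145, against an adjusted p of 0.963 with an estimated correlation. Psmb3 had g = -0.93 and Psmb5 had g = -0.76, both subunits of the core particle.

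Periportal genes, which are more active where blood enters the lobule, had 14 of 20 members lower and 6 higher, with a median g of -0.69 and a camera adjusted p of 0.00799; the adjusted p with an estimated correlation was 0.963. The exact permutation p was 0.0303 before adjustment. Pck1 and Asl, argininosuccinate lyase of the urea cycle (g = -1.67), are members, as are Sds, serine dehydratase (g = -1.41), and Ctsc, a lysosomal protease that was higher (g = 1.35). In the urea cycle, 7 of 8 members were lower, with a camera adjusted p of 0.0307 and an adjusted p of 0.963 with an estimated correlation. Beside Asl, Slc25a15, the ornithine carrier, had g = -0.86 and Ass1 had g = -0.82. In gluconeogenesis, 12 of 14 members were lower, with a camera adjusted p of 0.0307 and an adjusted p of 0.963 with an estimated correlation. Fbp1, fructose-bisphosphatase, had g = -1.38 there. In oxidative phosphorylation, 53 of 67 members were lower, with a camera adjusted p of 0.0431 and an adjusted p of 0.963 with an estimated correlation. Ndufb9 of complex I had g = -1.52 and Atp5f1b of the ATP synthase had g = -1.64. Under quantile normalization the mean moderated t of the proteasome, gluconeogenesis and oxidative phosphorylation lists turned above 0, while that of all genes was -0.26; under median centring, which moved the mean of all genes to 0.31, they also turned above 0, and gluconeogenesis and oxidative phosphorylation were not called (adjusted p = 0.124 and 0.758) while the proteasome was (adjusted p = 0.023). Without maple syrup replicate 3 camera called 2 lists in place of 7, and without sugar mix replicate 2, the animal with the highest interferon score (1.636), the interferon and proteasome lists each had an adjusted p of 0.12. Without maple syrup replicate 2 the interferon list had an adjusted p of 0.0575.

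**Figure D2:**
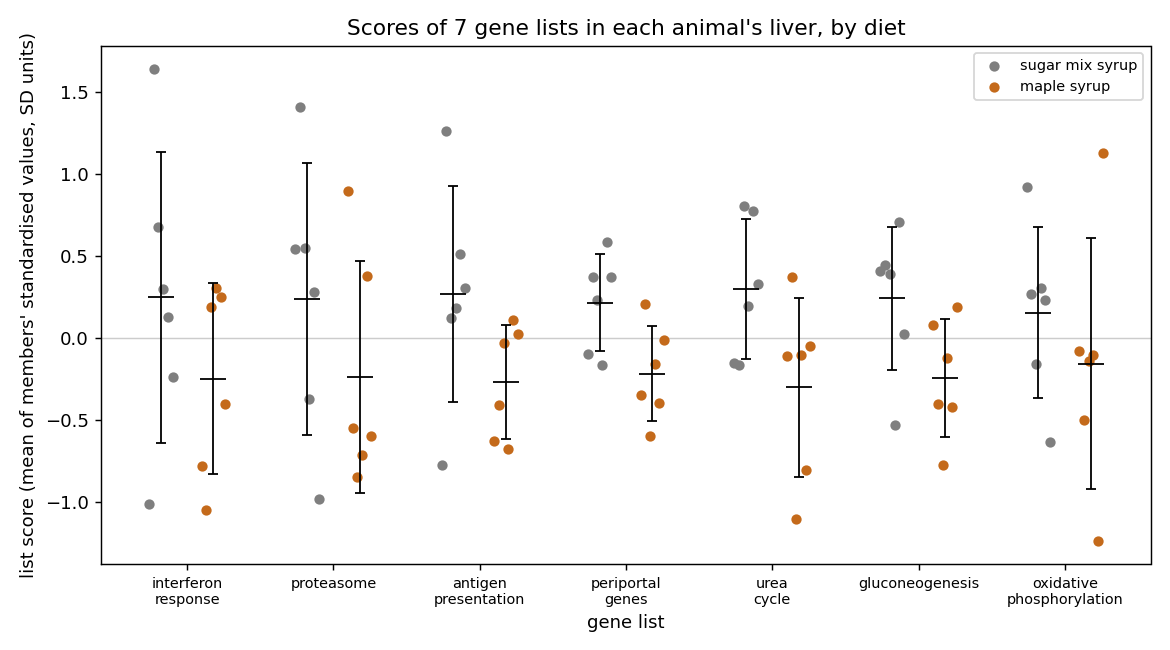
Scores of the 7 lists that passed camera with the preset correlation, as the mean of the members' standardised values (vertical axis, in standard deviations). Each point is 1 animal, with 6 per diet, and the bars are the mean and the standard deviation; the mean is lower with maple syrup in each list, -0.25 against 0.25 for the interferon response, while the animals of the diets overlap.

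The markers of other cell types in liver did not pass camera with the settings fixed beforehand; Kupffer cell and macrophage markers passed under median centring, with array weights and without maple syrup replicate 5, stellate cell markers under median centring, and sinusoidal endothelial and erythroid markers with single arrays left out. Kupffer cell and macrophage markers had 13 of 19 members lower and 6 higher, with a median g of -0.46 and an adjusted p of 0.251. The median has the sign of those of the interferon and antigen presentation lists, but no shift was established (exact permutation p = 0.463). Markers of sinusoidal endothelial cells had 14 of 19 members higher, with an adjusted p of 0.206, and those of erythroid cells and blood had 10 of 13 higher, with an adjusted p of 0.143. Hepatocyte markers had 6 of 13 members higher and 7 lower, with an adjusted p of 0.945. The adjusted p was 0.464 for stellate cells and fibroblasts, 0.470 for cholangiocytes, and 0.945 for neutrophils, T and NK cells, B and plasma cells, adipocytes and pancreatic acinar cells. Genes that respond to RNA quality and tissue handling had an adjusted p of 0.945. For the 5′ probe sets of the array's RNA controls, an exact permutation test between the diets gave p = 0.344 for beta-actin, 0.183 for GAPDH and 0.460 for hexokinase. Their standardised means with maple syrup and sugar mix were -0.28 and 0.28 for beta-actin, -0.39 and 0.39 for GAPDH, and 0.23 and -0.23 for hexokinase. With 6 animals per diet, differences of this size are not excluded.

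Other lists of liver metabolism and stress did not pass with the settings fixed beforehand. Amino acid degradation passed under median centring and without sugar mix replicate 2, maple syrup replicate 2 or maple syrup replicate 6, and inflammatory targets under median centring and without sugar mix replicate 1 or maple syrup replicate 5. The tricarboxylic acid cycle passed without sugar mix replicate 6 or maple syrup replicate 6, and ammonia-releasing catabolism under median centring. The heat shock response passed under median centring and without sugar mix replicate 6. Endoplasmic reticulum stress and insulin and fasting signalling passed under median centring. The ATF4 amino acid response passed without sugar mix replicate 5, cytosolic ribosomal proteins without sugar mix replicate 1 and the cell cycle without sugar mix replicate 4. The camera adjusted p was 0.143 for inflammatory and NF-kB targets, 0.278 for the tricarboxylic acid cycle, 0.312 for amino acid degradation, 0.594 for fatty acid and triglyceride synthesis, 0.741 for cholesterol synthesis and uptake, 0.645 for the ammonia-releasing catabolism of amino acids, 0.941 for liver injury enzymes and 0.941 for the NRF2 antioxidant response.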

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

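Of the tests in this part, these were chosen after the result was seen: the count of splits for called genes, the count of members that oxidative phosphorylation shares, the camera test with a correlation from scaled residuals, the removal of shared genes and the rescaling by the root of power 4.

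In 10 of 106 combinations of a diet and a gene or list, 1 animal lay far from the other 5 of its diet, where chance gives 5.3. The values are in standard deviations of the gene over the 12 animals. In the sugar mix group, Cps1 was at -1.25 in replicate 6, Fbp1 at -1.16 in replicate 4, Mdh1 at -1.68 in replicate 6, Psmb10 at 2.92 in replicate 2, Ndufb9 at 1.96 in replicate 1 and Psmd2 at -0.69 in replicate 4. In the maple syrup group, Rwdd3 was at -0.13 in replicate 1, Mdh1 at 0.85 in replicate 6, Cpt1a at 1.58 in replicate 5 and Cyp1a1 at 2.98 in replicate 1.

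The absence of called genes between the diets was weighed first. In limma 0 genes passed, and 616 had an unadjusted p under 0.05. Every split reaches a count of 0 (100 of 100, with at most 20 genes in another split), so the splits say nothing about this count. A scale that hides differences was tested by rescaling each gene's range by its root of power 4: 0 genes passed, although the prior degrees of freedom moved from 0.649 to 5.19. This rescaling is linear within a gene, so it leaves g unchanged and can act only through the variance that limma shares across genes. It therefore could not reveal differences that the scale hides within a gene. Compression that is not linear within a gene remains open.

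The lists called by camera were weighed second. Of 100 splits, 69 called at least the 7 lists of the real split, with 20 at most in another split and a median of 9, so chance cannot be excluded. Members that vary together between animals may account for the calls. With the correlation from scaled residuals 0 lists passed, although with limma's own estimate 1 list passed, which alone would have decided neither way. That list was the proteasome, for which limma's estimate was -0.0153 and the mean correlation from scaled residuals was 0.57. Its pass therefore rests on an estimate near no correlation, for members that varied together by the other estimate. Without the 9 genes shared between called lists 3 lists kept an adjusted p under 0.05, but the proteasome, 1 of these, shares 0 members and was not tested by this. Of the lists that hold shared genes, the interferon response and antigen presentation kept theirs, while gluconeogenesis went to an adjusted p of 0.357 and periportal genes to 0.583, for which shared genes may account, although smaller lists also lose power. The urea cycle fell under 5 members and was not tested. Oxidative phosphorylation also shares 0 members with the other called lists, and its unadjusted p stayed at 0.00615; its adjusted p went from 0.0431 to 0.0738 through the adjustment over the lists alone. Shared genes cannot be the source of the calls of the proteasome and oxidative phosphorylation, which hold none. Without shared genes the camera adjusted p was 0.00327 for the interferon response and 0.0129 for antigen presentation, which argues against this source for those lists. For gluconeogenesis, periportal genes and the urea cycle it is left undecided. An effect of the diet remains possible and these tests do not establish it.

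The genes called by rank products were weighed last. The 521 genes, 263 called higher and 279 lower with 21 in both, lay mostly among the widest ranges: 193 of them among the 200 widest and 488 among the 1000 widest. Splits with 3 arrays of each diet on both sides gave a median of 453 calls, between 323 and 672 in 50 splits, which is consistent with unequal spread between genes as the source. Of 100 splits, 30 called at least as many, with 821 at most in another split, so chance cannot be excluded. After each gene was scaled to a standard deviation of 1 the test called 0 genes, and after the rescaling by the root of power 4 it called 200.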

How the results depend on the processing

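Rescaling by the root of power 4, exact permutation of list scores, correlation from scaled residuals and the removal of shared members were chosen after seeing the data. No alternative of limma called a gene: the count was 0 in each, and between 0 and 0 with each array left out. Rank products called 521. Camera called 7 lists, and 0 under quantile normalization, 13 under median centring (5 of the original 7), 1 with the correlation as limma estimates it, 0 with fry, 0 with exact permutation, 0 with the correlation from scaled residuals and 3 without shared members. With the mean of a gene's probe sets it called 5 (urea cycle and gluconeogenesis lost) and without the intensity trend 5 (gluconeogenesis and oxidative phosphorylation lost). With each array left out it called 2 to 10, the 2 without maple syrup replicate 3. Over these 12 settings antigen presentation was called 12 times, the interferon response, proteasome and periportal lists 10 times each, the urea cycle 8, gluconeogenesis 6 and oxidative phosphorylation 4 times; the interferon response was lost without sugar mix replicate 2 or maple syrup replicate 2. The cause was not tested, except that quantile normalization leaves 964 genes (6.78%) constant and median centring raises the median standard deviation from 7.35e-06 to 3.61e-05, since array medians differ by more than most genes vary. The replicate numbers do not pair the animals: the correlations of same-numbered arrays were 0.12, 0.0216, -0.0196, 0.0299, 0.0869 and -0.0326, and 1 of 6 arrays in each diet correlated best with its own number. With the replicate number as a block limma called 0 genes and camera 3 lists (interferon response, antigen presentation, proteasome).

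Signs turned in 29 gene values and 6 list values. As 0 genes were called, none of the gene values could be of a called gene. The 6 list values all belong to called lists. Under quantile normalization the mean moderated t became 0.28 for gluconeogenesis, 0.42 for oxidative phosphorylation and 0.20 for the proteasome, and the moderated t became -0.84 for Nmur2, -0.70 for Scaf11, -1.88 for Hsd17b1, -0.24 for Dexi, 0.11 for Tap2, 2.38 for Ndufv2, 1.06 for Psmb3, 0.54 for Psmd2, 0.16 for Gpt and -0.57 for Igfbp1. Median centring subtracts 1 constant per array and moved the mean moderated t of all genes from -0.06 to 0.31 (quantile normalization to -0.26), so signs that turn under it are to be read against this common shift; the proteasome stayed called there (adjusted p = 0.023), and gluconeogenesis (0.124) and oxidative phosphorylation (0.758) did not. Under it the value became 0.03 for gluconeogenesis, 0.27 for oxidative phosphorylation, 0.03 for the proteasome, 0.28 for Pck1, 0.24 for Fbp1, 0.21 for Ndufb9, 0.31 for Atp5pb, 0.32 for Atp5f1b, 0.02 for Psmb5 and 0.34 for Ldha. With single arrays left out, Gpt ran from -0.64 to 0.41, Cpt1a from -0.44 to 0.65 and Hmox1 from -1.14 to 0.39.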

Other observations

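In these tests the sex-typical markers were chosen after the most variable genes and their enrichment had been seen, and the comparison of their scores by diet and the tests of the RNA controls were chosen after the scores had been seen, as was the correlation without shared genes.

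Akr1b7, an aldo-keto reductase, had the widest range over the 12 animals (2.90 in the deposited score), followed by Obp3, a lipocalin made in male rat liver, Dhrs7l1, Hamp, the iron hormone hepcidin, and Isg15, an interferon-induced ubiquitin-like protein. Among the 200 genes with the widest range, the growth hormone and IGF axis had 12 of its 24 measured members. The interferon response had 12 of 34, the list of phase I enzymes, mostly cytochromes P450 and including Fmo5 and Por, had 9 of 33 and amino acid degradation had 9 of 35. Because compression may differ between probe sets, ranges are not taken as comparable in size between genes, and these counts describe the deposited score only. The median correlation of a gene's 2 most variable probe sets was 0.35 over all 4526 genes with several, and 0.93 over the 122 genes whose second probe set also had wide spread; in the latter the larger standard deviation was a median of 1.66 times the smaller, and 4.75 times at the 90th percentile.

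Many growth hormone-dependent genes differ between the sexes in rat liver, and all animals here were male. The hypothesis was that they vary along one male-to-female pattern. The score of 6 male-typical genes (Cyp2c11, Cyp2c13, Cyp2a2, Cyp3a18, Obp3 and Hsd3b5) correlated with that of 6 female-typical genes (Cyp2c12, Cyp2c7, Cyp2a1, A1bg, Prlr and Onecut1) at r = -0.86 (permutation p = 7e-05, adjusted p = 0.00056) and rho = -0.92 (permutation p = 6e-05) over the 12 animals. Without the 2 animals farthest from the median, r was -0.88, and within diets it was -0.96 for maple syrup and -0.74 for sugar mix. The result is consistent with the hypothesis, but 10 of the 12 markers, among them all 6 male-typical ones, are among the 200 genes of widest range that prompted it, and Onecut1 hardly followed the pattern (r from -0.34 to 0.01 with the male-typical genes). In all, 8 relations were computed in this family.

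A difference in RNA integrity between arrays is not excluded as a candidate explanation. The first control tried, GAPDH, gave r = -0.25 (permutation p = 0.457; rho = -0.15) with the male-typical score and a 95% interval of -0.72 to 0.38, too wide to decide. Of the controls added next, beta-actin gave r = -0.33 (permutation p = 0.315; rho = -0.13), but the 5′ probe set of hexokinase gave r = 0.84 (permutation p = 0.00025, adjusted p = 0.001) and rho = 0.79 (permutation p = 0.00357), with r = 0.72 without the 2 farthest animals. Without the 2 farthest animals r was 0.47 for beta-actin and 0.18 for GAPDH. Over all animals hexokinase and the other controls had opposite signs. These are correlations with the male-typical score. Whether the controls' 5′ ends move together was not tested. The 3′ probe set of hexokinase gave r = 0.52 (permutation p = 0.0865; rho = 0.50), so a change in the level of this transcript is not told from integrity. No pattern here is called biological.

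The male-typical score was 0.42 ± 0.59 with maple syrup and -0.42 ± 0.92 with sugar mix (SD, n = 6 each; exact permutation p = 0.0714), and the female-typical score was -0.43 ± 0.65 and 0.43 ± 0.61 (SD, n = 6 each; exact permutation p = 0.0411). Adjusted over both scores, each exact p was 0.0714, so neither passed. Sugar mix replicate 2 had the lowest male-typical score, -2.22, and without it the differences went from 0.83 to 0.47 and from -0.86 to -0.72, with exact permutation p values of 0.143 and 0.0823. Interferon response and antigen presentation scores correlated at r = 0.77 (permutation p = 0.0037, adjusted p = 0.00987) and rho = 0.50 (permutation p = 0.0984), but the lists share 3 genes. Without these r was 0.69 (permutation p = 0.0136, adjusted p = 0.0272) and rho 0.43 (permutation p = 0.161), with r = 0.43 without the 2 farthest animals and 0.13 within maple syrup and 0.83 within sugar mix, so the relation rests on few animals. Akr1b7 and Obp3 gave r = -0.52 (permutation p = 0.0878) and rho = -0.48 (permutation p = 0.121), with r = -0.27 without the 2 farthest animals.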
